A study of Mus musculus with 18 samples.

How the data were processed

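The analysis started from a table of read counts per gene for 18 libraries of CD19+ cells of mouse spleen, 3 for each of 3 genotypes in DMSO or etoposide. Per the labels' protocols, CD19+ cells were selected from spleen suspensions, treated for 4 h, and sequenced as polyA RNA with a kit that marks the strand with dUTP. Per the submitters' processing notes, STAR 2.7.9a, deepTools 3.5.1 and limma were used, in roles that are not given, on build mm10 (GRCm38.p6). The counts the authors deposited are whole numbers that had not been scaled to library size. Of 54082 genes in the table, 53154 matched GENCODE M21 in identifier and coordinates and 214 were added immunoglobulin entries. The 1 entry without a gene was left out.

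Between 59.6% and 68.3% of the counts above 0 were even in each library, so both mates of a read pair appear to have been counted, and a count is not an independent molecule. Genes lying inside another gene showed how overlaps were counted. In 21 of 23 pairs on opposite strands the host gene had at least the count of the nested gene in every library. The same held in 8 of 14 pairs on the same strand, and some hosts were in more than 1 pair. For most of these pairs reads thus appear to have been counted over introns, without strand and for both genes, but not for all, since Gm20388 had fewer reads than Ankrd11, Rpl13, Tcf25 and Irf8 inside it in every library. Of 64 named genes that were followed through the other settings below, 7 overlapped a gene with at least 50% as many reads (Aicda, Bcl2a1d, Cdc25b, Ebi3, Rag1, Rag2 and mt-Co3), and their counts cannot be told from those of that gene. Rag1 and Rag2 lie in 1 such gene, so part of the reads of either may have come from it. Close copies such as the Bcl2a1 genes are uncertain in the same way.

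Groups were taken from the titles. The treatment tag of 7 libraries contradicts the title and the description, and the tag was tried as an alternative. Total counts were 64.2 to 136.6 M per library. The MN etoposide libraries held 64.2 to 73.8 M and had TMM factors of 1.47 to 1.656, against 0.732 to 1.091 elsewhere. Libraries of 1 group differed by more than counting error (chi-square per degree of freedom 13.5 to 178.4), so none was a copy of another. Errors between replicates therefore exceed those set by depth.

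All comparisons came from 1 model of 6 groups in edgeR 4.0.16 under R 4.3.3, without a replicate block. Genes were filtered with filterByExpr, which left 35257, counts were scaled by TMM, and quasi-likelihood F tests with robust dispersions (common dispersion 0.1303) gave two-sided p-values, adjusted by the Benjamini-Hochberg method over the genes tested within a comparison. A gene was called at an adjusted p under 0.05. Of the 10 comparisons, 3 set etoposide against DMSO within a genotype, 3 tested the difference of these responses between genotypes, and 4 set MN or 3SA against WT within a treatment. Log2 fold changes came from the edgeR fit. A prior count of 2 was used for the log2 CPM of the list tests, the naming rule and the check of pairing. CPM are TMM-scaled. Equivalence of responses was judged by 95% confidence intervals of their difference inside -1 to 1. Genes called equivalent met this bound, which a lost response smaller than 1 can also meet.

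The 29 gene lists, the tests, the rule for naming genes and most of the other settings below were fixed before the data were examined. The lists cover p53 targets, NF-kB targets, NF-kB pathway components, immediate early genes, interferon stimulated genes, the BCL2 family, death receptors and the TNF family, DNA repair, proliferation, the integrated stress and unfolded protein responses, heat shock, cholesterol synthesis, trafficking, mitochondrially encoded mRNAs, markers of B cell identity and of 6 B lineage subsets or stages, and markers of T, NK, monocyte, neutrophil, dendritic, erythroid, platelet and stromal cells. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a comparison. With the correlation estimated from the data, 2 of the 146 list calls held: p53 targets in the WT response and erythroid markers in 3SA against WT in DMSO. Named genes were drawn from the 10 higher and 10 lower with the largest change among called genes of at least 5 mean CPM that changed the same way in all same-numbered differences or did not overlap between groups, and from the 4 list members with the smallest p. Predicted genes, immunoglobulin segments, ribosomal protein genes and pseudogenes were not named by that rule. Genes behind the counts of 8 or fewer between 3SA and WT were named after their values were seen.

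Other settings were no filter on low counts, DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, fits on the compared groups only, immunoglobulin genes left out, a replicate block, a log2 fold change of at least 1, and each library left out in turn. Chosen after the data were seen were subtraction of background reads, sex as a covariate, genes of at least 5 mean CPM, and both libraries of WT replicate 3 left out. Background was the density of reads over 30 long autosomal genes silent in B cells, most of them neuronal. For each library it was multiplied by the span of a gene and taken from its count, which removed 9.8% to 15.1% of the reads of MN etoposide libraries and 0.2% to 3.7% of others and left 30634 genes to test. Sex was read from Xist and Y-linked genes: of the 3 replicate numbers of each genotype, 2 of WT, 1 of 3SA and 1 of MN were female.

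The edgeR model was tested on simulated counts for 34102 genes with 50 genes of at least 1 mean CPM seeded at each fold. No difference of background between groups was simulated. For etoposide against DMSO in WT it recovered 14% at 1.5-fold, 46% at 2-fold, 72% at 3-fold and 86% at 4-fold, with 3 false calls elsewhere. For the MN minus WT difference it recovered 0%, 22%, 52% and 70%, with 1 false call. Across genes, which are not independent replicates, the fold change of a comparison had a Spearman correlation of -0.01 to 0.13 with gene span and of -0.29 to 0.02 with GC content, over the 98% of genes with a value.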

Results

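PolyA RNA was sequenced from CD19+ B cells of mouse spleen after 4 h in DMSO or in 10 µg/mL etoposide, a topoisomerase II poison that leaves DNA double-strand breaks. The cells came from wild-type mice (WT), from mice with a mutant Nemo allele written Nemo3SAΔT in the labels (3SA), and from mice with a floxed Nemo gene and Cre in the mb-1 locus (Mb1cre+Nemoflox, MN). Each of the 6 groups held 3 libraries, 18 in all. Summed counts per library ran from 64.2 to 136.6 M, and 35257 genes were tested. Nemo, encoded by Ikbkg, is the regulatory subunit of the IkB kinase complex that activates NF-kB. The series asks whether the phosphorylation of SQ motifs in Nemo by the kinase ATM is needed for the expression changes that Nemo brings about after double-strand breaks. Values below are log2 fold changes ± SE with edgeR adjusted p-values (n = 3 libraries per group) unless stated otherwise.

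Ikbkg (ENSMUSG00000004221.16, chromosome X, 74393290 to 74453854, mm10) had 136.8 ± 13.8 CPM (counts scaled to library size by TMM, mean ± SD, n = 3) in WT DMSO libraries, 126 ± 4.08 in 3SA and 84.4 ± 9.08 in MN. In etoposide it had 149 ± 20.1 CPM in WT, 126 ± 2.83 in 3SA and 56.1 ± 6.36 in MN. MN libraries thus held 61.7% of the WT level in DMSO (-0.7 ± 0.11, adjusted p = 0.000743) and 37.7% in etoposide (-1.41 ± 0.11, adjusted p = 5.49e-09). The further drop in etoposide depends on the scaling. TMM factors, by which CPM are divided, were 1.47 to 1.656 in MN etoposide and 1.012 to 1.091 in MN DMSO. In WT they were 0.732 to 0.92 in etoposide and 0.846 to 0.989 in DMSO. Ikbkg in 3SA did not differ from WT (adjusted p = 0.853 in DMSO and 0.432 in etoposide). Cd79a, whose mb-1 locus carries the Cre, stood at 52.8% of WT in MN in DMSO (-0.92 ± 0.15, adjusted p = 0.000755). The counts cover whole genes, so they do not show which part of Ikbkg was lost. Ikbkg overlaps G6pdx on the other strand, which had 36.7% as many reads, so part of its counts may be reads of G6pdx. A treatment tag in the labels contradicts the titles of 7 libraries (the etoposide library of 3SA replicate 3 and all 6 MN libraries), and the titles were followed. Cdkn1a, a p53 target (chromosome 17, 29090976 to 29100727), was high in every library titled etoposide, at 691 ± 213 CPM in WT, 644 ± 34.6 in 3SA and 126 ± 17.1 in MN. In DMSO it stood at 8.09 ± 1.32, 10.97 ± 1.038 and 9.99 ± 1.53.

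**Figure D1:**
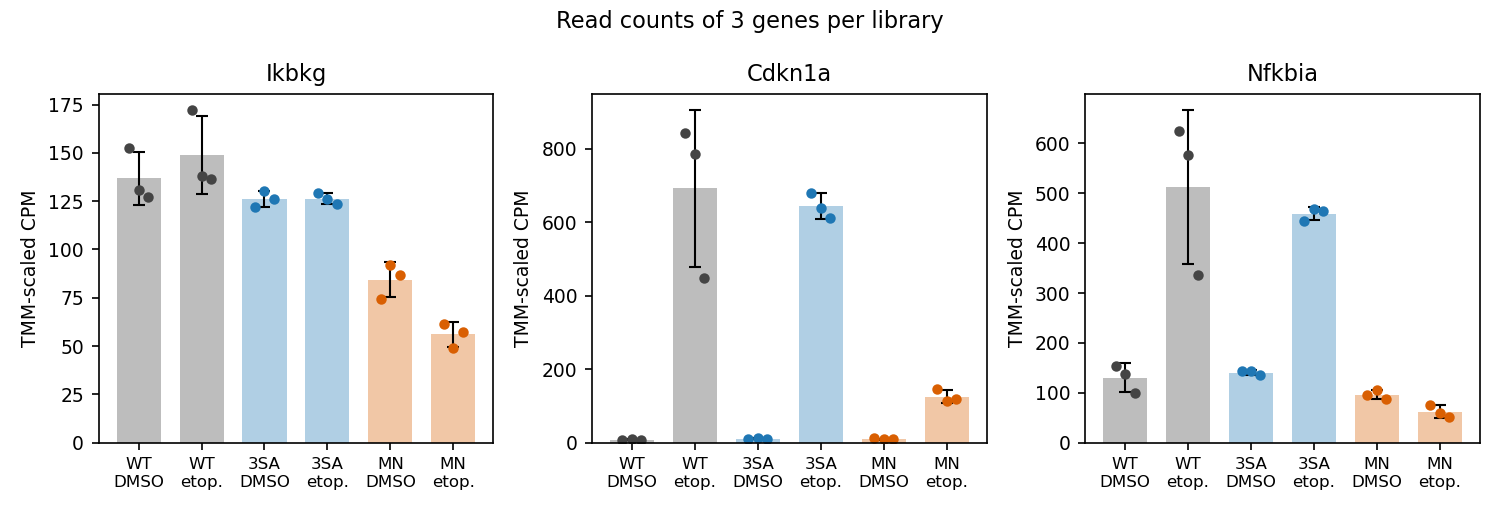
TMM-scaled CPM of Ikbkg, Cdkn1a and Nfkbia (vertical axes) in the 6 groups of 3 libraries (horizontal axes). Points are libraries, bars are group means and error bars are SD. Ikbkg was lower in MN, Cdkn1a rose with etoposide in each genotype, and Nfkbia rose from 130 to 512 CPM in WT and from 141 to 459 in 3SA and was 95.9 in DMSO and 62.3 in etoposide in MN. Drops from MN DMSO to MN etoposide depend on the scaling, with TMM factors of 1.012 to 1.091 and 1.47 to 1.656.

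Etoposide raised p53 and NF-kB target genes in WT B cells and lowered genes of B cell identity. The largest rises included Phlda3, a p53 target that restrains Akt (8.28 ± 0.47, adjusted p = 9.93e-09), Tnfsf4, which encodes OX40 ligand (6.75 ± 0.45, adjusted p = 3.99e-08), and Cdkn1a, the cyclin-dependent kinase inhibitor p21 (6.42 ± 0.23, adjusted p = 5.77e-13). Psrc1 rose by 6.71 ± 0.4, the ephrin receptor gene Epha2 by 5.94 ± 0.3 and the damage-induced apoptosis suppressor gene Ddias by 5.15 ± 0.14. Among the largest falls were the recombinase genes Rag1 (-5.12 ± 0.38, adjusted p = 1.32e-07) and Rag2 (-5.07 ± 0.52), the inhibitory receptor gene Cd22 (-3.46 ± 0.24, adjusted p = 8.28e-09) and the phosphatase gene Cdc25b (-3.49 ± 0.25). In total 4897 genes were higher and 2655 lower, and the median over all genes tested was 0.23. DESeq2 size factors moved that median by -0.11 and gave 3395 genes higher and 3140 lower, a share of 52% higher in place of 64.8%. After background subtraction 3555 were higher and 3891 lower, and genes with a mean of at least 5 CPM gave 3401 and 3558. A fit on the compared groups only gave 2064 and 2129. The balance of directions thus depended on the scaling, the genes and the libraries used.

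Of 50 p53 targets, 34 rose and 4 fell in WT (36 and 5 adjusted over the list alone, median 2.05, camera adjusted p = 1.55e-20, adjusted p = 0.0449 with an estimated correlation). Ccng1 (3.69 ± 0.12) and Plk2 (3.48 ± 0.12) were among them. Of 64 NF-kB targets, 48 rose and 3 fell (50 and 3 adjusted over the list alone, median 1.02, camera adjusted p = 3.47e-14, adjusted p = 0.335 with an estimated correlation). They included the death receptor gene Fas (4.49 ± 0.18), the adhesion gene Icam1 (3.65 ± 0.25) and the costimulatory receptor gene Cd40 (2.34 ± 0.23). Of the 64, 32 were also on other lists, and Fas was on that of p53 targets. Of 18 BCL2 family genes, 9 rose and 3 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.536 with an estimated correlation). Pro-apoptotic Bax (2.69 ± 0.12) and Bbc3 (4.62 ± 0.26) rose beside anti-apoptotic Bcl2l1 (3.62 ± 0.28). The immediate early genes had 14 of 24 members higher and 0 lower (14 and 2 adjusted over the list alone, camera adjusted p = 0.00102, adjusted p = 0.422 with an estimated correlation). Jun rose by 2.92 ± 0.25. Of 19 cholesterol synthesis genes, 13 rose and 1 fell (the same counts adjusted over the list alone, camera adjusted p = 0.000259, adjusted p = 0.422 with an estimated correlation). Msmo1 rose by 1.33 ± 0.13 and Sqle by 1.28 ± 0.15. Stress genes also rose: 14 of 24 genes of the integrated stress and unfolded protein responses were higher and 2 lower (17 and 2 adjusted over the list alone, camera adjusted p = 0.000224, adjusted p = 0.372 with an estimated correlation). Further, 8 of 14 heat shock genes were higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 0.00128, adjusted p = 0.335 with an estimated correlation).

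B cell identity and receptor signalling genes went the other way, with 22 of 27 lower and 2 higher in WT (22 and 2 adjusted over the list alone, median -0.9, camera adjusted p = 2.94e-19, adjusted p = 0.085 with an estimated correlation). The kinase gene Blk changed by -1.55 ± 0.13, the IgM Fc receptor gene Fcmr by -1.85 ± 0.16 and Fcrla by -2.06 ± 0.18. Lymphocyte trafficking genes had 7 of 20 lower and 3 higher (8 and 3 adjusted over the list alone, camera adjusted p = 0.000224, adjusted p = 0.335 with an estimated correlation). After background subtraction 11 were lower and 3 higher. S1pr4 changed by -2.47 ± 0.17 and Cd69, an activation marker, by 1.68 ± 0.18. Follicular B cell markers had 6 of 10 lower and 3 higher (camera adjusted p = 0.000638). Marginal zone markers had 6 of 15 lower and 2 higher (camera adjusted p = 0.000447), and both stood at an adjusted p = 0.335 with an estimated correlation. Adjusted over the list alone, the counts of these 2 lists were the same. Of 318 immunoglobulin segments 37 fell and 0 rose by edgeR.

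NF-kB pathway components had 22 of 44 higher and 4 lower (camera adjusted p = 0.00124, adjusted p = 0.611 with an estimated correlation). Death receptor and TNF family genes had 12 of 25 higher and 3 lower (camera adjusted p = 0.00128, adjusted p = 0.335 with an estimated correlation). Proliferation genes split into 11 higher and 13 lower (camera adjusted p = 0.0205, adjusted p = 0.611 with an estimated correlation), and lost the call after background subtraction (10 higher, 17 lower, camera adjusted p = 0.0751). Ccnd2 changed by 2.77 ± 0.26 and Ccne1 by -2.8 ± 0.3. Transitional and immature B cell markers had 5 of 17 higher and 6 lower (camera adjusted p = 0.0137, adjusted p = 0.335 with an estimated correlation). T cell markers had 0 of 20 higher and 2 lower (camera adjusted p = 0.00968, adjusted p = 0.536 with an estimated correlation). No camera call was made for DNA repair (17 higher, 4 lower), interferon stimulated (1, 2), germinal center and activated B cell (8, 3), plasma cell (4, 3), B1 (1, 1), NK (0, 0), monocyte (2, 4), neutrophil (1, 0), dendritic (2, 2), erythroid (1, 1), platelet (1, 1) and stromal (1, 1) lists, nor for mitochondrially encoded mRNAs (0, 0).

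In 3SA cells etoposide likewise raised p53 and NF-kB target genes and lowered B cell identity genes. Phlda3 rose by 6.88 ± 0.44, Tnfsf4 by 6.26 ± 0.44, Cdkn1a by 5.87 ± 0.22 (adjusted p = 1.62e-12) and Fas by 4.23 ± 0.17 (adjusted p = 4.01e-12), and Rag1 (-3.89 ± 0.36) and Cd22 (-3.28 ± 0.23) fell. Of 50 p53 targets 37 were higher and 6 lower (the same counts adjusted over the list alone, median 2.19, camera adjusted p = 7.32e-17, adjusted p = 0.076 with an estimated correlation). Of 64 NF-kB targets 45 were higher and 3 lower (46 and 4 adjusted over the list alone, median 0.87, camera adjusted p = 1.21e-07, adjusted p = 0.504 with an estimated correlation). Icam1 rose by 3.48 ± 0.24 and Cd40 by 2.13 ± 0.23. B cell identity genes had 22 of 27 lower and 2 higher (23 and 2 adjusted over the list alone, camera adjusted p = 1.2e-19, adjusted p = 0.076 with an estimated correlation). In total 5655 genes were higher and 3211 lower, and the median over all genes was 0.43. With DESeq2 size factors, which moved that median by -0.18, 3371 were higher and 4205 lower, a share of 44.5% higher in place of 63.8%. Of the 4897 genes higher in WT, 3803 (77.7%) were also higher in 3SA, against 785 for independent lists. Of the 2655 lower in WT, 2450 (92.3%) were lower in 3SA, against 242.

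The difference between the 3SA and WT responses, tested directly, passed the threshold for 0 genes by edgeR. At an unadjusted p under 0.05 there were 1279 genes, limma-voom called 0, and DESeq2's Wald test called 4, named after their values were seen: Gm15221, Gm18201 and Gm49217 higher and Tspan33 lower. The 1279 became 4821 without WT DMSO replicate 1 and 2593 without WT etoposide replicate 3, with 0 called by edgeR in both fits. No single target passed the threshold: Cdkn1a stood at -0.54 ± 0.26, Bax at -0.25 ± 0.16, Plk2 at -0.49 ± 0.15, Tnf at -0.73 ± 0.37 and Rag1 at 1.23 ± 0.47, each at an adjusted p = 0.995. Camera called 13 lists, all lower in 3SA, of which heat shock genes and marginal zone markers lost the call after background subtraction (camera adjusted p = 0.0742 and 0.121). NF-kB targets had a median difference of -0.22 (camera adjusted p = 7.83e-05) and p53 targets -0.13 (camera adjusted p = 0.000996). Interferon stimulated genes had a median of -0.67 (camera adjusted p = 1.61e-06). Between 3SA and WT cells their median was 0.73 in DMSO (camera adjusted p = 1.9e-08, adjusted p = 0.754 with an estimated correlation) and 0.03 in etoposide (camera adjusted p = 0.87). Cholesterol synthesis genes had -0.23, proliferation genes -0.14 and erythroid markers -0.37, each at a camera adjusted p = 0.000996. In the difference of responses each of these 6 lists stood at an adjusted p = 0.669 with an estimated correlation, and 0 of their members passed adjusted over the list alone. Of the 7552 genes that responded in WT, 6042 (80%) had a 95% confidence interval of the 3SA minus WT difference inside -1 to 1, and the median distance from estimate to limit was 0.44. For MN minus WT 1967 (26%) did. The bound is wider than the median WT change (0.81 over genes higher and -0.89 over genes lower), and 3051 genes changed by at least 1. An interval inside it thus does not show that a smaller response was kept. Only 3 had an interval of the 3SA minus WT difference wholly outside -1 to 1 (Gm25862 higher in 3SA, Gm3164 and Tspan33 lower, each at an adjusted p = 0.995). That number depended on the setting: it was 20 without WT DMSO replicate 1, 12 without WT DMSO replicate 3, 11 after background subtraction and 32 with DESeq2. In simulated data this comparison recovered 20% of 50 genes seeded with a 2-fold difference, 54% at 3-fold and 72% at 4-fold. Seeded genes had a mean of at least 1 CPM, so recovery may be lower over all genes tested.

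**Figure D2:**
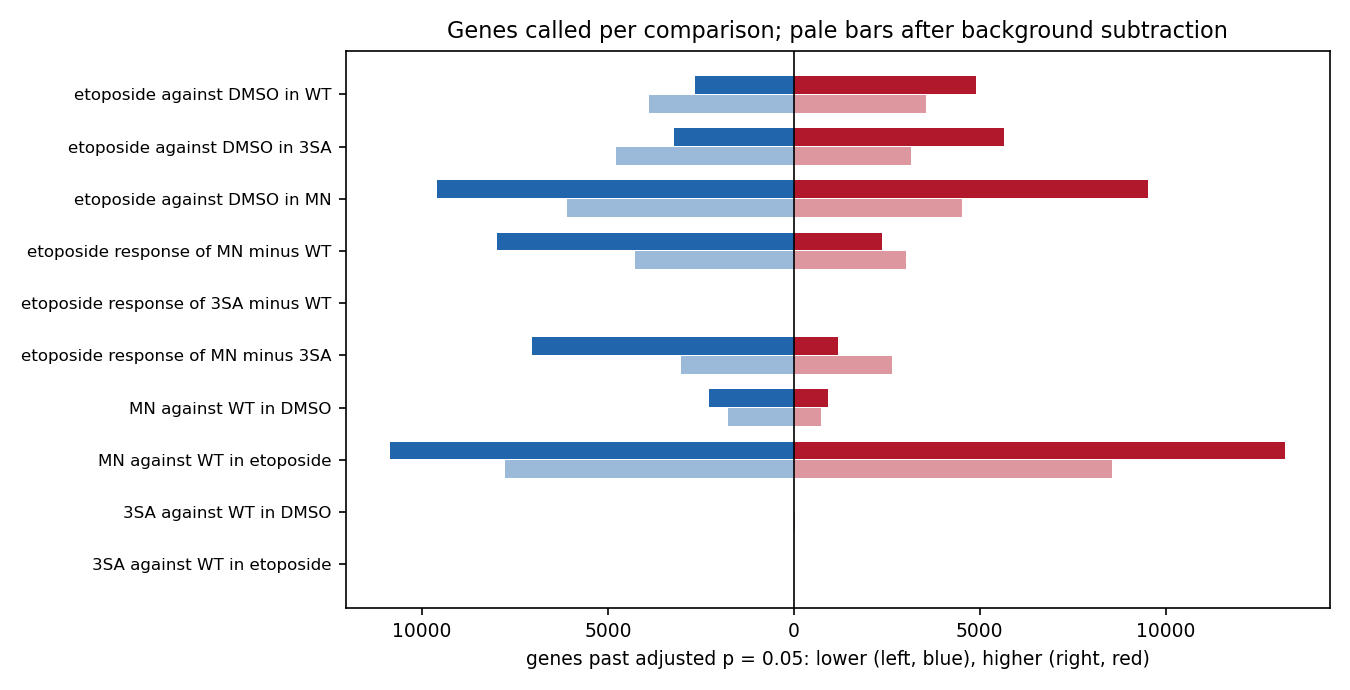
Number of genes past an adjusted p of 0.05 (horizontal axis, lower to the left, higher to the right) in each comparison of groups of 3 libraries. Dark bars give the counts as deposited, and pale bars those after the background measured over silent genes was subtracted. Subtraction changed the MN response from 9531 higher and 9602 lower genes to 4526 and 6112, and the difference between 3SA and WT responses had 0 genes both ways.

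In MN cells etoposide raised p53 targets, by less than in WT, while NF-kB targets did not rise as a group. Phlda3 rose by 5.56 ± 0.42, Cdkn1a by 3.65 ± 0.2 (adjusted p = 1.34e-09), Bbc3 by 3.86 ± 0.25 and Bax by 1.55 ± 0.11. The p53 targets had 35 of 50 higher and 9 lower (36 and 10 adjusted over the list alone, median 1.52, camera adjusted p = 4.35e-06, adjusted p = 0.263 with an estimated correlation). Of 64 NF-kB targets 4 were higher and 33 lower (the same counts adjusted over the list alone, median -0.42, camera adjusted p = 8.24e-05, adjusted p = 0.59 with an estimated correlation). The lymphotoxin gene Ltb changed by -1.92 ± 0.14 and the NF-kB target Birc3 by -1.15 ± 0.11. All 27 B cell identity genes were lower (27 adjusted over the list alone, camera adjusted p = 2.82e-14, adjusted p = 0.2 with an estimated correlation), among them Syk (-1.54 ± 0.11) and Blk (-1.53 ± 0.13). Cholesterol synthesis genes had 0 of 19 higher and 15 lower (the same counts adjusted over the list alone, camera adjusted p = 1.36e-05, adjusted p = 0.422 with an estimated correlation). The mitochondrially encoded mRNAs had 0 of 13 higher and 10 lower (the same counts adjusted over the list alone, camera adjusted p = 0.000233, adjusted p = 0.263 with an estimated correlation).

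The MN etoposide libraries carried more background reads than the others. Over 30 long autosomal genes silent in B cells they had 7.48 ± 1.95 reads per kb (mean ± SD, n = 3), against 0.82 ± 0.28 in WT etoposide, 1.2 ± 0.08 in 3SA etoposide and 1.82 ± 0.64 in MN DMSO. They held at least 10 reads for 33766 to 35617 genes. In total 9531 genes were higher and 9602 lower in MN, with a median of 0.66 over all genes. Without MN DMSO replicate 2 the higher genes fell to 5426. After subtraction of this background from every count 4526 were higher and 6112 lower. NF-kB targets then had 7 members higher and 22 lower with a median of -0.02 (camera adjusted p = 0.146), so their call in MN was lost. The p53 targets then had 32 higher and 6 lower (median 1.65), B cell identity genes 25 lower, cholesterol synthesis genes 8 lower and mitochondrially encoded mRNAs 7 lower. Genes with a mean of at least 5 CPM alone gave 3796 higher and 2782 lower. DESeq2 size factors moved the median over all genes by 0.13 in MN.

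**Figure D3:**
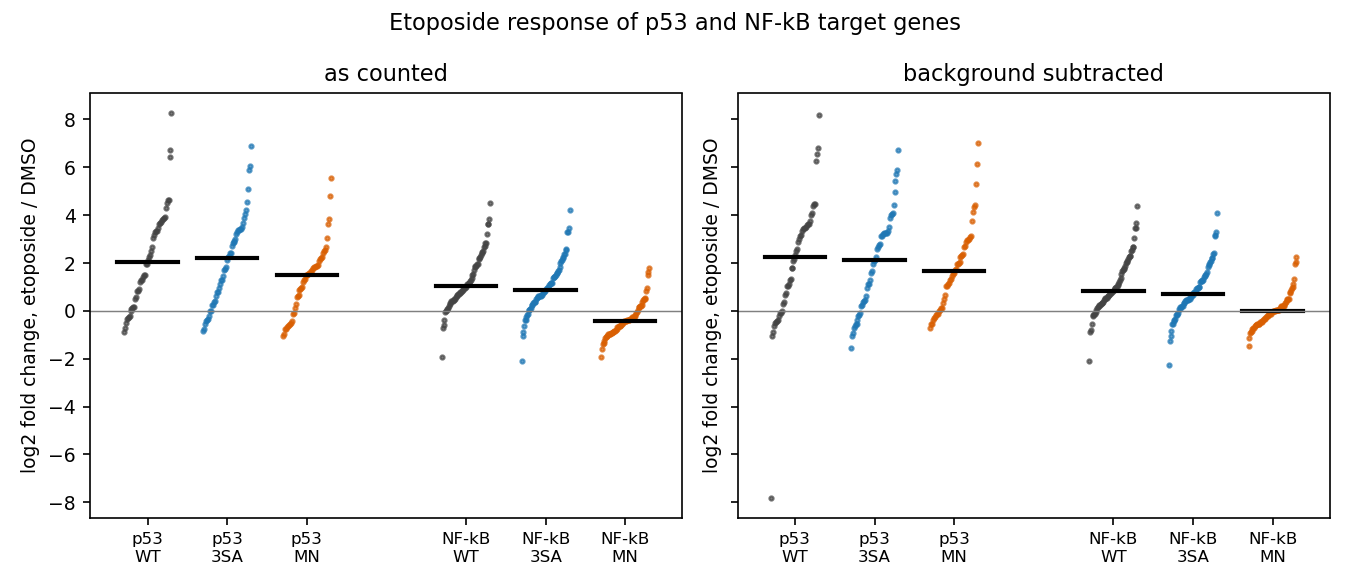
Log2 fold change of each p53 target and each NF-kB target (vertical axes) with etoposide in WT, 3SA and MN (n = 3 libraries per group), as counted on the left and with the background subtracted on the right. Points are genes in order of size, and lines are medians. As counted, NF-kB medians were 1.02 in WT, 0.87 in 3SA and -0.42 in MN, and -0.02 in MN after subtraction.

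NF-kB targets responded less in MN than in WT. Over all genes the largest differences included Tnfsf4 (-4.71 ± 0.54, adjusted p = 1.03e-05) and the interleukin receptor gene Il2ra (-3.77 ± 0.36, adjusted p = 1.41e-06), neither on the NF-kB list. Cd40 (-3.46 ± 0.32, adjusted p = 9.47e-07) and Bcl2l1 (-3.45 ± 0.37, adjusted p = 3.72e-06), both on it, were also among them. After background subtraction these 4 genes stood at -4.3, -3.35, -2.88 and -2.99, and all kept their call. Differences in the other direction included Rag1 (3.77 ± 0.47, adjusted p = 2.16e-05) and Cd22 (1.82 ± 0.3), which fell less in MN. Of 64 NF-kB targets 0 were higher and 53 lower in the difference (1 and 54 adjusted over the list alone, median -1.59, camera adjusted p = 2.73e-17, adjusted p = 0.33 with an estimated correlation). After subtraction the counts were 2 and 47 (median -1). Fas, which is on the p53 list too, differed by -2.69 ± 0.22 and Nfkbie, an NF-kB inhibitor, by -2.43 ± 0.26. p53 targets had 2 of 50 higher and 32 lower (3 and 33 adjusted over the list alone, median -1.07, camera adjusted p = 8.92e-09, adjusted p = 0.33 with an estimated correlation). After subtraction they had 5 higher and 21 lower (median -0.52). Cdkn1a differed by -2.77 ± 0.26 and Bax by -1.14 ± 0.16. Cholesterol synthesis genes had 0 of 19 higher and 16 lower (0 and 17 adjusted over the list alone, camera adjusted p = 2.55e-09, adjusted p = 0.33 with an estimated correlation). Hmgcs1 differed by -1.82 ± 0.17. The mitochondrially encoded mRNAs had 0 of 13 higher and 10 lower (the same counts adjusted over the list alone, median -1.04, camera adjusted p = 0.00046, adjusted p = 0.33 with an estimated correlation), and 0 and 5 after subtraction (median -0.42). Stromal markers had 2 of 16 higher and 0 lower (the same counts adjusted over the list alone, median 1.29, camera adjusted p = 0.0187, adjusted p = 0.442 with an estimated correlation), and lost the call after subtraction (1 and 0, camera adjusted p = 0.0534). T cell markers had 7 of 20 higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.00496, adjusted p = 0.448 with an estimated correlation), and 12 and 0 after subtraction. In total 2359 genes were higher and 7996 lower, and after subtraction 3010 and 4270. DESeq2 size factors, which moved the median over all genes by 0.25, gave 4498 higher and 5844 lower, a share of 43.5% higher in place of 22.8%. The DESeq2 Wald test gave 6480 and 6471, and genes with a mean of at least 5 CPM gave 4236 higher and 2785 lower (60.3% higher), so the balance of directions depended on the scaling and the genes kept. It also depended on single libraries: with 1 left out, the higher genes ran from 1186 (without MN DMSO replicate 2) to 7032 (without WT DMSO replicate 1), and the lower genes fell to 4348 without MN etoposide replicate 3.

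The receptor and survival genes Cd40, Il2ra and Bcl2l1, like Tnfsf4, also responded less in MN than in 3SA. Tnfsf4 differed by -4.22 ± 0.53 (adjusted p = 3.53e-05), Il2ra by -3.63 ± 0.36, Cd40 by -3.24 ± 0.32 (adjusted p = 2.99e-06) and Bcl2l1 by -3.14 ± 0.37 (adjusted p = 1.32e-05) in the response of MN minus that of 3SA. NF-kB targets had 1 of 64 higher and 51 lower (2 and 51 adjusted over the list alone, median -1.43, camera adjusted p = 1.35e-15, adjusted p = 0.37 with an estimated correlation), and 2 and 39 after subtraction. p53 targets had 0 of 50 higher and 27 lower (0 and 32 adjusted over the list alone, median -0.87, camera adjusted p = 8.92e-08, adjusted p = 0.349 with an estimated correlation), and 4 and 15 after subtraction (median -0.28). In total 1197 genes were higher and 7053 lower, against 2636 and 3040 after subtraction, and 2156 and 3748 with DESeq2 size factors, which moved the median over all genes by 0.32 and the share of higher genes from 14.5% to 36.5%. Genes with a mean of at least 5 CPM gave 3371 higher and 2273 lower (59.7% higher), so this balance also depended on the genes kept. The total of 8250 fell to 4218 without MN etoposide replicate 2 and to 4208 without MN etoposide replicate 3, with 2730 and 2728 lower.

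Genes called in WT and again, with the opposite sign, in the MN minus WT difference were taken as those whose WT response depended on the Nemo genotype. There were 4467, of which 3846 rose and 621 fell in WT. In 3SA 3560 of them (79.7%) were called in the WT direction, 4445 had the WT sign, and 0 were called in the 3SA minus WT difference by edgeR (2 by DESeq2 on its own list, Gm18201 and Tspan33), while 4132 were called in MN minus 3SA. The median share of the WT change was 0.85 in 3SA and -0.63 in MN. The genes were chosen for an MN minus WT difference against the WT change, so the MN share is low by construction. The list was chosen on WT libraries, which favours WT. Chosen on 3SA libraries instead, 3645 genes were found, 3465 of them (95.1%) were called in WT in the same direction, and the median shares of the 3SA change were 1.11 in WT and -0.58 in MN. On this list too the MN share is low by construction. The MN minus WT and MN minus 3SA differences share the MN libraries. With simulated unchanged groups 66.7% of genes had the same sign in both. There 0 genes were called in either difference alone, so the 0 called in both says nothing on overlap from shared libraries. The simulation also held no difference of background between groups. The count fell from 4467 to 2614 without MN etoposide replicate 2, to 2586 without MN etoposide replicate 3 and to 2024 when each comparison was fitted on its own groups only, and it was 3919 after background subtraction. The split into rises and falls moved from 3846 and 621 to 2432 and 1487 after subtraction and to 2406 and 1004 with DESeq2 size factors.

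Before damage, MN cells differed from WT in markers of B cell subsets and in proliferation genes. Among the largest differences in DMSO were the recombinase genes Rag2 (3.04 ± 0.41, adjusted p = 0.000159) and Rag1 (2.61 ± 0.33, adjusted p = 0.000231), both higher in MN. Lower in MN were Fcrl5 (-3.41 ± 0.5, adjusted p = 0.000984), Myc (-2.63 ± 0.36, adjusted p = 0.000525) and Bcl2a1d (-2.6 ± 0.27, adjusted p = 2.33e-05). Anti-apoptotic Bcl2 was lower too (-1.73 ± 0.15, adjusted p = 1.22e-06). Transitional and immature B cell markers had 9 of 17 higher and 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 4.26e-05, adjusted p = 0.0942 with an estimated correlation). Vpreb3 (1.44 ± 0.18) and Cd24a (0.88 ± 0.12) were among the higher ones. Marginal zone markers had 7 of 15 lower and 2 higher (8 and 3 adjusted over the list alone, camera adjusted p = 0.00012, adjusted p = 0.139 with an estimated correlation). Cd9 (-2.26 ± 0.19), Cd36 (-1.28 ± 0.12) and Dtx1 (-0.96 ± 0.14) were among the lower ones. B1 markers had 9 of 12 lower and 1 higher (9 and 2 adjusted over the list alone, camera adjusted p = 7.43e-06, adjusted p = 0.0942 with an estimated correlation). Of 64 NF-kB targets 27 were lower and 2 higher (40 and 3 adjusted over the list alone, camera adjusted p = 1.59e-15, adjusted p = 0.183 with an estimated correlation), with Cd83 at -1.63 ± 0.22. Of 44 proliferation genes 16 were lower and 0 higher (29 and 0 adjusted over the list alone, camera adjusted p = 4.09e-13, adjusted p = 0.101 with an estimated correlation).

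Markers of other blood cells moved with the genotype in these libraries. In MN DMSO libraries 10 of 17 erythroid markers were higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 5.03e-07, adjusted p = 0.101 with an estimated correlation), with Slc4a1 at 2.2 ± 0.35. There 6 of 19 neutrophil markers were higher and 0 lower (16 and 0 adjusted over the list alone, camera adjusted p = 3.19e-06, adjusted p = 0.214 with an estimated correlation). T cell markers had 11 of 20 lower and 0 higher (14 and 1 adjusted over the list alone, camera adjusted p = 1.13e-08, adjusted p = 0.101 with an estimated correlation). In total 913 genes were higher and 2274 lower in MN than in WT in DMSO. This count of 3187 depended on single libraries: it was 1137 without MN replicate 1, 1252 without MN replicate 3, 1153 without WT replicate 1, 1392 without WT replicate 2 and 9079 without WT replicate 3. Without the last, 4757 were higher and 4322 lower, so the balance of directions depended on that library.

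In etoposide, MN and WT cells differed in 24065 genes, 13213 higher and 10852 lower, and after background subtraction in 8568 higher and 7764 lower. Rag1 (6.38 ± 0.4, adjusted p = 4.27e-09) and Rag2 (6.65 ± 0.54, adjusted p = 6.14e-09) were higher in MN. The low-affinity IgE receptor gene Fcer2a (-7.37 ± 0.89, adjusted p = 1.06e-05), Ebi3 (-5.28 ± 0.25, adjusted p = 8.56e-11) and Bcl2a1d (-5.25 ± 0.3) were lower. Of 64 NF-kB targets 59 were lower and 1 higher (the same counts adjusted over the list alone, median -2.04, camera adjusted p = 3.83e-18, adjusted p = 0.218 with an estimated correlation), and 53 and 3 after subtraction. Cd40 differed by -3.93 ± 0.25 and Cd83 by -4.3 ± 0.24. Erythroid markers had 13 of 17 higher and 0 lower (camera adjusted p = 0.0046, adjusted p = 0.279 with an estimated correlation). Neutrophil markers had 16 of 19 higher and 1 lower (camera adjusted p = 0.0101, adjusted p = 0.488 with an estimated correlation). Both lists had the same counts adjusted over the list alone. Of all 35257 genes tested 13213 were higher, and background stood at 7.48 reads per kb in MN etoposide against 0.82 in WT etoposide. Such background can raise genes with few reads, so these 2 counts do not show more erythroid or neutrophil transcripts in MN. B cell identity genes had 6 of 27 higher and 11 lower (median -0.09, camera adjusted p = 0.248), and 17 higher and 5 lower after subtraction (median 0.63, camera adjusted p = 0.0221), so their direction depended on the background.

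3SA and WT cells differed in few genes within a treatment. In DMSO 7 were higher and 1 lower in 3SA by edgeR, with 2553 genes at an unadjusted p under 0.05, 71 by DESeq2 and 10 by limma-voom. Among them were the red cell genes Slc4a1 (3.48 ± 0.37, adjusted p = 0.000333), Aqp1 (3.41 ± 0.43, adjusted p = 0.00266), Gypa (3.06 ± 0.44, adjusted p = 0.00754), Hemgn (2.94 ± 0.4) and Epb42 (2.9 ± 0.48). Others were the scavenger receptor gene Cd36 (0.84 ± 0.12) and the predicted gene 5730455P16Rik (2.29 ± 0.09, adjusted p = 1.04e-11, chromosome 11, 80360492 to 80378034). The lower gene, Platr4, was near 0 counts in 3SA and has no usable error. Erythroid markers had 3 of 17 higher and 0 lower (13 and 0 adjusted over the list alone, median 1.59, camera adjusted p = 1.1e-30, adjusted p = 0.00216 with an estimated correlation). Neutrophil markers had a median of 1.59 with 0 members past the threshold (3 adjusted over the list alone, camera adjusted p = 1.9e-08, adjusted p = 0.599 with an estimated correlation). In etoposide 5 genes were higher and 1 lower by edgeR, with 3968 at an unadjusted p under 0.05, 269 by DESeq2 and 1 by limma-voom. They were 5730455P16Rik (2.49 ± 0.09, adjusted p = 2.66e-12), Aqp1, Slc4a1, Cd36 and mt-Co3 higher, and the respiratory chain gene Cox7a2 lower (-0.87 ± 0.14, adjusted p = 0.0323).

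WT replicate 3 stood apart in these last comparisons. Without both of its libraries 583 genes differed between 3SA and WT in DMSO (258 higher, 325 lower) and 2624 in etoposide (485 higher, 2139 lower), while the difference of the 2 responses still held 0. By sex genes it was the only male of WT, while 3SA had 1 female and 2 males. Without it WT is all female, so these counts cannot be told from a difference of sex or from another trait of this animal. Camk2b set it apart in DMSO, at 5.389 CPM against 1335 and 1608 in the other WT replicates. That gene did not follow sex, with 1466 to 4035 CPM in 3SA and 3.818 to 35.43 in MN libraries of both sexes. The DMSO library of WT replicate 3 also had the most reads (136.6 M) and the highest background of the WT libraries (2.02 reads per kb). The DMSO count of 8 was also 5 without 3SA replicate 2 (5730455P16Rik, Aqp1, Gypa, Hemgn and Slc4a1), 35 without WT replicate 1, 2 without WT replicate 2 (5730455P16Rik and Slc4a1) and 19 without WT replicate 3. The etoposide count of 6 was 701 without WT replicate 3 and between 1 and 3, always with 5730455P16Rik, without any other library. Cd36, Slc4a1 and Cox7a2 in etoposide and Epb42, Gypa and Hemgn in DMSO were among the genes that lost their call when single libraries were left out. After background subtraction Aqp1 (edgeR adjusted p = 0.344), Epb42 (0.419) and Platr4 (0.5) lost it in DMSO. In etoposide Aqp1 (0.139) and Slc4a1 (0.0676) did, and the other called genes kept it. Background reads over silent genes stood at 0.62 ± 0.16 per kb in 3SA DMSO against 1.03 ± 0.93 in WT DMSO.

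**Figure D4:**
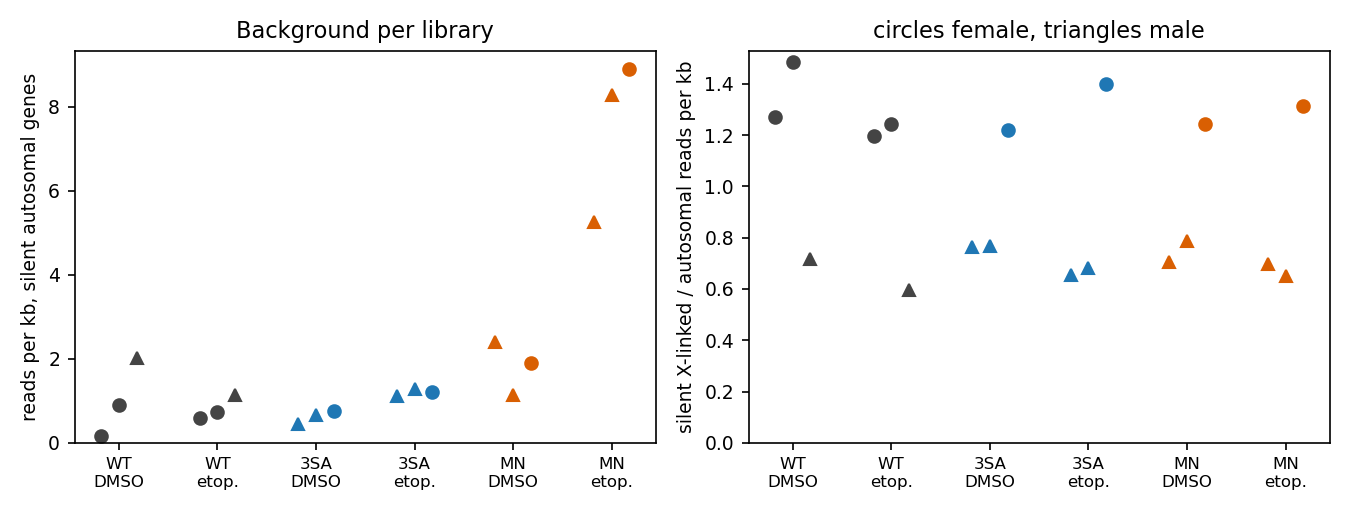
Reads per kb over 30 silent autosomal genes (left) and the ratio of reads per kb over 15 silent X-linked genes to those over the autosomal genes (right), for each of 18 libraries by group. Circles are libraries from females and triangles from males, by Xist and Y-linked genes. MN etoposide libraries had 5.25 to 8.9 reads per kb, and in all groups the ratio was 0.6 to 0.79 in males and 1.19 to 1.48 in females.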

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

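In this part the tests of NF-kB against p53 targets, the use of X-linked reads against a rise of transcription, and the settings with background subtraction, sex or without WT replicate 3 were chosen after related results had been seen. The etoposide response differed between MN and WT for 10355 genes and between MN and 3SA for 8250, by the edgeR test of the difference itself. Of the genes that responded in WT, 4467 had an MN minus WT difference of the opposite sign to the WT change, which includes genes that only responded less in MN. Of the named genes with the largest differences of response, 20 came from MN minus WT and 20 from MN minus 3SA. A signal outside the genes compared was the density of 7.48 reads per kb over silent autosomal genes in MN etoposide libraries, above that of all other groups.

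More genes at low counts in the MN etoposide libraries fit reads from genomic DNA: over silent X-linked genes the density relative to autosomal genes was 0.65 and 0.7 in the 2 male MN etoposide libraries (median 0.67) and 1.31 in the female one, as the number of X chromosomes would give. The same split was seen in all libraries (0.6 to 0.79 in 10 from males, 1.19 to 1.48 in 8 from females), so background of this kind may be in every group in different amounts. Library size was excluded by the totals themselves. MN etoposide libraries held 64.2 to 73.8 M and had 33766 to 35617 genes with 10 or more reads, while other libraries held at least 73.7 M and had at most 31421. Thinning to the smallest total, that of an MN etoposide library, added little, with at least 33766 there against at most 30021 elsewhere. A broad rise of transcription in Nemo-deficient cells met the bound written for it, as 8568 of 13213 genes stayed higher in MN after subtraction, but as the whole cause it was excluded by the X-linked ratio. After subtraction and thinning the MN etoposide libraries still had 27223 to 28089 such genes, against at most 24270 elsewhere, so a part due to transcription or to incomplete subtraction may remain.

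The smaller rise of NF-kB targets in MN than in WT did not come from background reads as the whole cause, since 47 of the 53 members called lower in the difference kept the call after subtraction. A response weaker by the same log2 amount for NF-kB and p53 targets could not be told apart: without shared members the medians of MN minus WT were -1.29 and -1.01 (n = 32 and 37 genes, permutation p = 0.048), and -0.69 and -0.45 after subtraction (permutation p = 0.13). Values argued against a response weaker by the same proportion as the only change. Among members higher in WT the median share of the WT change kept in MN was -32.1% for NF-kB and 57.3% for p53 targets (n = 21 and 24 genes, permutation p = 3e-05). After subtraction it was 5.2% and 74.7% (n = 20 and 21, permutation p = 5e-05). An equal log2 shift in MN, as from scaling, takes a larger share from smaller rises, so it was not excluded. Without shared members the WT medians were 0.82 for NF-kB and 1.52 for p53 targets. These permutations treat genes as independent, which they are not. The Nemo genotype remained a possible explanation, but B cell subset markers already differed before damage, and the 2 could not be separated here.

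The lower marginal zone B cell markers in MN in DMSO were not explained by unequal sex of the animals, since 7 of the 7 members called lower kept the call with sex as a covariate. Of all genes called lower 71.7% did. Without WT replicate 3, 7 of 7 kept it, but so did 99.7% of all genes called lower (2268 of 2274). That test could therefore not show a part played by this animal. After background subtraction 7 of 7 kept it too, against 74.4% of all genes called lower. The list lost its call with an estimated correlation (adjusted p = 0.139), and neutrophil and erythroid markers were higher in the same libraries, so a changed mixture of cells could not be excluded. The genotype, through Nemo or through the Cre in the mb-1 locus, remained a possible explanation.

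Relabelling could not test the counts of genes, as there were too few splits: 10 into 3 and 3 in each comparison, so the share that calls as many genes could not go under 0.05. In the WT response 1 split, the real one, called as many (7552, highest other 963). The same held, with 1 split each and a highest other of 0, for the responses of 3SA (8866) and MN (19133), for MN minus WT (10355), MN minus 3SA (8250), and MN against WT in DMSO (3187) and in etoposide (24065), and with 1 split and a highest other of 1 for 3SA against WT in etoposide (6). For the 3SA minus WT difference all 10 splits called as many as the real one, that is 0 by edgeR, where 1279 genes had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 4. For 3SA against WT in DMSO 3 splits called as many as the real 8, and the highest other called 729, with WT replicate 1 beside 3SA replicates 1 and 2, which points to structure among the libraries other than genotype. That split sorts the libraries by background: 0.17 to 0.67 reads per kb over silent genes on this side, 0.75 to 2.02 on the other. Whether background was the cause was not tested.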

How the results depend on the processing

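In this part the settings with background subtraction, a sex covariate, at least 5 CPM or without WT replicate 3 were chosen after the data were seen. Each setting changes the genes, libraries or scaling used, and the cause of a change was not tested. With fits on only the groups compared, counts were 4193 for the WT response (2064 higher, 2129 lower), 751 for MN against WT in DMSO, 4 for 3SA against WT in DMSO (5730455P16Rik, Aqp1, Gypa, Slc4a1), 2 in etoposide (5730455P16Rik, Tmsb10), 2024 for Nemo-dependent genes and 3379 for equivalent genes. These genes were named after the values were seen. A log2 fold change of at least 1 gave 3051 for WT, 4456 for 3SA, 10855 for MN, 6341 for MN minus WT, 4001 for MN minus 3SA and 1256 for MN against WT in DMSO, as a stricter test must. With DESeq2 there were 4 for 3SA minus WT, 6498 for MN against WT in DMSO, and 71 and 269 for 3SA against WT in DMSO and etoposide, where limma-voom called 1 in etoposide (5730455P16Rik). Subtraction gave 10638 for MN and 27 for 3SA against WT in DMSO. At least 5 CPM left fewer genes and gave 6578 for MN, 9886 for MN against WT in etoposide, and 25 and 12 for 3SA against WT in DMSO and etoposide. Without WT replicate 3 there were 10518 for MN against WT in DMSO, and 583 and 2624 for 3SA against WT in DMSO and etoposide.

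With treatment by its tag, which swaps all MN libraries and mixes 3SA, directions turned by construction in MN (16668, 8608 higher and 8060 lower), MN minus WT (11592) and MN minus 3SA (14008). The 3SA response then had 0 genes by edgeR, as an etoposide library sat among the DMSO ones. MN against WT had 24183 in DMSO and 8952 in etoposide, and 3SA against WT had 4 in DMSO (5730455P16Rik, Aqp1, Hemgn, Slc4a1) and 1 in etoposide (5730455P16Rik). Single genes of MN were not given under the tag. Background subtraction turned the median of the B cell identity and BCR list in MN against WT in etoposide from -0.09 to 0.63.

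With each library left out in turn, counts ran from 5835 to 8198 for WT, 6482 to 7538 for 3SA, 13965 to 18391 for MN, 6997 to 15419 for MN minus WT, 0 to 0 for 3SA minus WT, 4208 to 7798 for MN minus 3SA, 1137 to 9079 and 20859 to 23533 for MN against WT in DMSO and etoposide, 2 to 35 and 1 to 701 for 3SA against WT, 2586 to 5473 for Nemo-dependent genes and 4768 to 6385 for equivalent genes. Of 115 values of named genes 108 were called. All 115 kept direction and their side of the threshold under the DESeq2 Wald test, and calls were lost by 7 with limma-voom, 8 with only the groups compared, 5 after subtraction, 3 with sex, 2 with DESeq2 size factors and 1 without a filter. Of 846 values with a library left out 34 lost a call, and 17 of 29 values did with the tag. Of 290 list results, 146 called, 29 lost and 14 gained a call after subtraction, 144 lost it with an estimated correlation, and fry lost 40 and gained 31.

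The replicate block changed no total by more than 1.5 times, though the higher genes in MN against WT in DMSO went from 913 to 1460. For MN or 3SA against WT the block was the replicate number across genotypes, which joins different animals. Deviations of same-numbered libraries of 2 genotypes correlated by -0.36 to 0.2, so those totals do not check a pairing. Totals were 8487 for WT, 10596 for 3SA, 19912 for MN, 10788 for MN minus WT, 0 for 3SA minus WT, 9156 for MN minus 3SA, 3956 and 23879 for MN against WT, 8 and 9 for 3SA against WT, 5121 for Nemo-dependent and 7133 for equivalent genes. Under it 1 of 108 calls of genes named here and 1 list call were lost and 10 list calls gained, and no other call given here changed. Beyond these, genes passed or lost the threshold: of the higher genes, 4743 of 4897 kept the call in WT and 1844 of 2359 in MN minus WT. The pairing rests on shared numbers only: deviations correlated by 0.28 to 0.44 in WT, 0.03 to 0.12 in 3SA and -0.1 to 0.24 in MN, 6 of 9 correlated best with their own number, and sex genes matched in 9 of 9, a hint from the data and not the design.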

Other observations

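In this part the tests after background subtraction were chosen after the data were seen, and the genes and lists shown were picked after their values were seen. Cd80 rose by 3.8 ± 0.23 and Cd83 by 2.42 ± 0.22 in WT. The difference of MN minus WT was -2.59 ± 0.29 for Cd80, -2.66 ± 0.3 for Cd83, -2.01 ± 0.25 for Cd69 and -2.66 ± 0.33 for the transcription factor gene Irf4, each at an adjusted p under 0.0001. Among immediate early genes, Fos rose in MN (2.39 ± 0.22, adjusted p = 4.07e-07) and Egr3 fell (-1.82 ± 0.15, adjusted p = 8.9e-08). In MN minus WT, Jun stood at -2.47 ± 0.33 and Fos at 1.49 ± 0.3. Of 38 interferon stimulated genes 0 were higher and 19 lower in MN (the same counts adjusted over the list alone, median -1.26, camera adjusted p = 0.000181, adjusted p = 0.609 with an estimated correlation), and 0 and 8 after background subtraction. Lymphocyte trafficking genes had 0 of 20 higher and 18 lower in MN (the same counts adjusted over the list alone, camera adjusted p = 4.78e-06, adjusted p = 0.239 with an estimated correlation), and 0 and 11 after subtraction. NK cell markers, before subtraction, had 6 of 16 higher and 0 lower in MN (camera adjusted p = 0.0223, adjusted p = 0.59 with an estimated correlation). Background stood at 1.82 reads per kb in MN DMSO and 7.48 in MN etoposide, so this rise cannot be told from background.

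In DMSO, plasma cell markers were lower in MN than in WT, with 6 of 15 lower and 0 higher (8 and 0 adjusted over the list alone, camera adjusted p = 1.83e-05, adjusted p = 0.0942 with an estimated correlation). Xbp1 was among them (-0.74 ± 0.13, adjusted p = 0.00116). Germinal center and activated B cell markers had 6 of 17 lower and 1 higher (9 and 2 adjusted over the list alone, camera adjusted p = 0.000259, adjusted p = 0.0942 with an estimated correlation). The higher one was the deaminase gene Aicda (1.96 ± 0.28, adjusted p = 0.000253). Heat shock genes had 5 of 14 lower and 0 higher (8 and 0 adjusted over the list alone, camera adjusted p = 4e-06, adjusted p = 0.101 with an estimated correlation). Genes of the integrated stress and unfolded protein responses had 12 of 24 lower and 1 higher (15 and 1 adjusted over the list alone, camera adjusted p = 1.04e-07, adjusted p = 0.139 with an estimated correlation). Of 318 immunoglobulin segments 189 were lower and 11 higher with etoposide in MN, and 186 lower and 26 higher in MN than in WT in etoposide. Camk2b split the WT libraries: it stood at 1335 and 1608 CPM in DMSO and 721.8 and 741.2 in etoposide in WT replicates 1 and 2, and at 5.389 and 7.74 in replicate 3. Camk2b stood at 1466 to 4035 in the 3SA libraries and at 3.818 to 35.43 in the MN libraries.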
